A study of Bos taurus with 6 samples.

How the data were processed

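Total RNA from the longissimus dorsi of 6 steers, 3 Japanese Black and 3 Holstein, was treated with DNase, converted to biotin-labelled cRNA and hybridised to Affymetrix arrays, 1 per animal, per the labels' protocols. The deposited table holds 1 linear intensity per probe set and array for 24128 probe sets. Per the submitters' processing notes, GCOS 1.1.1 and Affymetrix Expression Console 1.1 were used; the algorithm that summarised the probes and any scaling target are not given in the sources used here. The deposited intensity values are never negative, and some are exactly 0. No further scaling between arrays was applied in the main fit. The upper quartile of the signals was 205 in Japanese Black 3 and 172 to 181 in the other arrays. Quantile normalization and median centring were therefore of interest as alternatives. Detection calls were not used here. The breed of each array was taken from the labels, and the replicate numbers 1 to 3 only name the animals.

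The 112 control probe sets were left out, which left 24016. An offset of 16 was added to each intensity before log2 was taken, and the 25% of probe sets with the lowest mean log2 over all arrays were left out, which left 18012. The breeds were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), two-sided, with Benjamini-Hochberg adjustment over all probe sets tested and a threshold of 0.05. Standard errors and 95% intervals are limma's moderated ones, with 4.91 prior degrees of freedom. The series design names a paired t-test. The labels do not say which animals form a pair, so the comparison was unpaired, and paired versions were run under all 6 possible matchings.

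Gene names came from the platform annotation provided with the table. Of the 24016 probe sets 13292 had 1 gene symbol, 86 several and 10638 none. No gene was named from a probe set with several. Gene identifiers of 13283 probe sets matched the RefSeq table of assembly ARS-UCD2.0, which changed 0 symbols. No coordinates are given because no genome build is named for the table.

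There were 24 gene lists with 718 different genes, of which 564 were named in the annotation. They cover lipid metabolism, energy metabolism, fibre types, muscle growth and turnover, stress responses and the other cell types that a muscle sample holds. Each gene was represented by its probe set of highest mean, 8050 genes in all. Lists were tested with camera at an inter-gene correlation of 0.01 and at least 5 genes, adjusted over the lists. Camera with an estimated correlation and fry, a rotation test, were run beside it. The level of a list is the mean log2 of its genes in an array.

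Named genes followed a rule. It took the 12 probe sets per direction with 1 named gene, an adjusted p under 0.05 and no overlap between the breeds that had the largest difference, 1 per gene. Where fewer passed, the number was filled up to 12 with the smallest unadjusted p among non-overlapping probe sets, and each of these is said not to pass. Up to 4 genes with the smallest p were named per list. FABP4 and the histocompatibility genes of Holstein 3 were chosen after their values were seen. Lists, rule, the tests of probe sets and lists and most alternatives were fixed before the data were examined. Most tests of explanations were chosen after the results were seen.

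The limma step was tested on simulated data for the comparison of Japanese Black with Holstein, 18012 probe sets with the real means and spreads. Each probe set was drawn independently, so the share of false calls need not hold for real arrays, where genes vary together. In each of 5 runs 200 probe sets were changed. It recovered 0.896% of probe sets changed by 0.5 on the log2 scale, 37.0% of those changed by 1 and 88.5% of those changed by 2; 13 of 432 calls were false. On simulated data with independent genes, camera called a list shifted by 0.3 in 20 of 20 runs over 8050 genes, with 0 calls in 480 tests of unshifted lists.

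The alternatives were offsets of 1 and 64, no filter or the dimmer 50% left out, quantile normalization, median centring, other variance models, array weights, leaving out each array in turn, the plain t-test, a threshold of 0.10, a minimum of 1.5-fold, 1 probe set per gene and other list tests. The level of the adipocyte list as a covariate was added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.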

Results

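The series measured gene expression in the longissimus dorsi, a long back muscle, of steers from 2 cattle breeds. Japanese Black is a beef breed known for fat deposited within the muscle, and Holstein is a breed kept mainly for milk. Each breed was represented by 3 steers, with 1 array per animal, and all 6 animals had received energy-rich feed. The comparison therefore asked how the muscle of the breeds differed under that feeding; no steers on another feed were analysed here, so no response to the feed itself could be measured. The median signal of an array lay between 48.5 and 54.7 intensity units. Between 247 and 372 of 24016 probe sets per array were listed at 0. The small number of arrays limits the precision of every value below. The log2 differences are Japanese Black minus Holstein on the log2(signal + 16) scale, which understates the change of dim probe sets.

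ASIP, which encodes the agouti signalling protein, an antagonist of melanocortin receptors, was higher in Japanese Black muscle. Its signal was 194 ± 54.5 (SD, n = 3) in Japanese Black and 23.7 ± 8.13 (SD, n = 3) in Holstein. The log2 difference was 2.40 (SE 0.23), a 5.27-fold difference on that scale, with an adjusted p of 0.0361. It was 1.54 with an offset of 64 and 3.004 with an offset of 1. The lowest Japanese Black animal had a signal of 152 and the highest Holstein animal 32.0. RRAD, which encodes a small Ras-related GTPase that binds calcium channel subunits, was lower in Japanese Black muscle. Its signal was 3076 ± 409 (SD, n = 3) in Japanese Black and 7221 ± 611 (SD, n = 3) in Holstein. The log2 difference was -1.23 (SE 0.13), a 2.35-fold difference, with an adjusted p of 0.0449. A further probe set for class I genes of the major histocompatibility complex passed toward Japanese Black (adjusted p 0.0361). Its annotation lists several genes, so none is named. It read 77.6 ± 15.7 (SD, n = 3) in Japanese Black, while 2 of the Holstein animals were listed at 0 and the other at 10.4. The offset sets the size of this difference, so none is given.

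These 3 were the probe sets past an adjusted p of 0.05 among 18012 tested, 2 higher and 1 lower in Japanese Black. After quantile normalization 2 passed in each direction. At an unadjusted p under 0.05 there were 2267 probe sets, 1316 higher and 951 lower in Japanese Black, where 901 were expected by chance. This balance was not stable: it was 800 higher and 1125 lower without Japanese Black 3, 1165 and 1095 with array weights, and 1580 and 817 after median centring. Hybridisation controls and the 3′ to 5′ ratio of actin also separated the breeds, as given with the array values at the end. The breeds did not overlap for 3568 probe sets, or 19.8% of those tested, where chance gives 10% on average. Probe sets vary together, so the share in a single split can lie far from that average. The count past the adjusted threshold depended on single animals. It was 0 without Japanese Black 1, 2 or 3, 1 without Holstein 3, 2 without Holstein 1 and 15 without Holstein 2. These counts included 0 of the 3 probe sets above without Holstein 3, 1 without Holstein 1 and all 3 without Holstein 2. Across the 6 leave-one-out fits ASIP kept a log2 difference between 2.20 and 2.54 with adjusted p between 0.0391 and 0.161. RRAD stayed between -1.31 and -1.12 with adjusted p between 0.0472 and 0.161. Each passed only when Holstein 2 was left out. The count was also 0 with an offset of 1 and with the dimmer 50% of probe sets left out. Without the intensity trend RRAD did not pass (adjusted p 0.104) and ASIP did (0.0456). Without moderated variances neither passed (adjusted p 0.385 for each).

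**Figure D1:**
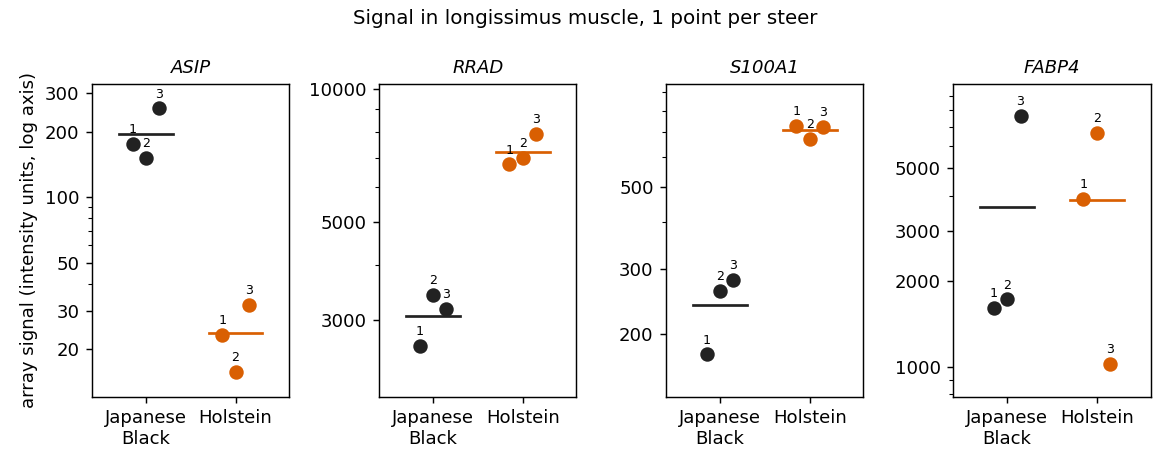
Array signal in intensity units on a log axis for ASIP, RRAD, S100A1 and FABP4 in each steer, with the replicate number at each point and a line at the breed mean. The breeds are separate for ASIP, RRAD and S100A1, whereas FABP4 spans 1021 to 6646 within the Holstein animals and 1615 to 7635 within the Japanese Black animals.

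Beyond ASIP, the genes with the smallest p toward Japanese Black did not pass the adjusted threshold. The adjusted p of these genes lay between 0.107 and 0.144. All 3 animals of each breed were on separate sides because the rule took only such genes. BOLA-N, a class I gene of the cattle histocompatibility complex, had a log2 difference of 2.99 (SE 0.43), with signals of 448 ± 101 (SD, n = 3) against 49.98 ± 37.5 (SD, n = 3). GHR, the growth hormone receptor, had a difference of 1.65 (SE 0.25) at its brightest probe set, whose signal was 356 ± 142 (SD, n = 3) against 97.5 ± 5.78 (SD, n = 3). Its 3 other probe sets, all dimmer, had differences between -0.24 and -0.12, so the probe sets of this gene disagreed in direction. NCEH1, a neutral cholesterol ester hydrolase, was higher at both probe sets, with a difference of 1.44 (SE 0.29, adjusted p 0.195) at the brighter one, which the rule did not choose. MTUS1, which encodes a microtubule-associated protein, had a difference of 1.07, and its 3 other probe sets had differences of 0.39, 0.61 and 0.72. NDUFS3, a subunit of respiratory complex I, had a difference of 1.51 at a probe set reading 223 ± 31.3 against 69.8 ± 24.8 (SD, n = 3 each). Its far brighter probe set differed by -0.03. The acetyltransferase gene KAT2B was higher at a dim probe set, against 0.29 and 0.26 at its brighter ones. The remaining genes were NKIRAS1 (1.37), TRAK2, a mitochondrial transport adaptor, GNB4, OFCC1 and RAB26. Where the Holstein signals are dim the offset sets the size of the difference. With offsets of 64 and 1 it was 0.83 and 2.68 for TRAK2, 0.75 and 1.71 for GNB4, 0.52 and 1.53 for OFCC1, and 0.52 and 1.49 for RAB26. It was 0.60 and 1.72 for KAT2B, 1.03 and 2.47 for the dimmer NCEH1 probe set and 2.20 and 3.52 for BOLA-N.

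Toward Holstein, 11 genes besides RRAD were taken by the same rule, with adjusted p between 0.0825 and 0.172, and none of them passed. S100A1, a calcium-binding protein of striated muscle, had log2 differences of -1.53 (SE 0.19) and -1.63 (SE 0.26) at its 2 probe sets. At the first, the signal was 239 ± 55.1 (SD, n = 3) in Japanese Black and 709 ± 31.2 (SD, n = 3) in Holstein. S100A2, of the same protein family, had a difference of -1.31. DNAJB5, a co-chaperone of heat shock proteins, had a difference of -1.67 with signals of 449 ± 76.9 against 1517 ± 526 (SD, n = 3 each). NMRK2, a nicotinamide riboside kinase of muscle, had a difference of -0.77 at a bright probe set reading 4303 ± 273 against 7402 ± 1393 (SD, n = 3 each). IFITM1, an interferon-inducible membrane protein, had a difference of -1.72, and COL5A3, a collagen chain, one of -0.90. ISOC2 had a difference of -1.57 and ANP32E, a histone chaperone, one of -0.91. For 3 genes the other probe sets did not share the difference. ESPL1, which encodes separase, had -1.29 at one probe set and -0.01 at the other. PGS1, an enzyme of cardiolipin synthesis, was lower at a probe set dim in Japanese Black, against -0.03 and -0.08 at the others. ATAT1, a tubulin acetyltransferase, had -0.93 against -0.24 and -0.03. With offsets of 64 and 1 the difference was -0.66 and -1.76 for PGS1, -0.90 and -1.50 for ESPL1, and -0.62 and -1.07 for ANP32E.

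**Figure D2:**
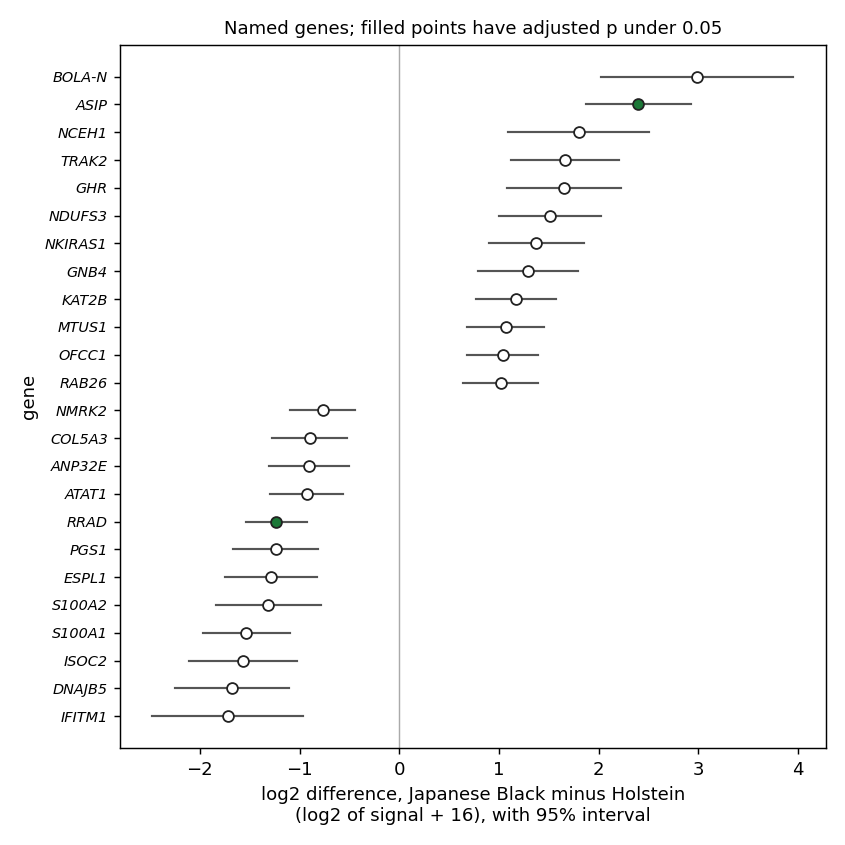
Log2 difference of 24 named genes, Japanese Black minus Holstein, on the x axis, with 95% intervals from limma as lines and 1 gene per row. Filled points, ASIP at 2.40 and RRAD at -1.23, have an adjusted p under 0.05; open points do not. All are drawn with an offset of 16, which sets the size for dim genes.

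Genes of adipocytes and lipid droplets varied far more between animals than between breeds. Of 24 measured members 14 were higher and 10 lower in Japanese Black, with a median log2 difference of 0.08 and an adjusted p of 0.539, and 0 passed, also when adjusted over the list alone. The median was -0.25 without Japanese Black 3, -0.23 without Holstein 3, 0.42 without Japanese Black 1, 0.29 without Japanese Black 2, 0.16 without Holstein 1 and 0.44 without Holstein 2, with adjusted p between 0.0811 and 0.359. FABP4, the fatty acid binding protein of adipocytes, read 1615, 1726 and 7635 in the Japanese Black animals and 3899, 6646 and 1021 in the Holstein animals. The mean level of the list was 0.92 above the mean of all arrays in Japanese Black 3, 0.49 above it in Holstein 2 and 0.80 below it in Holstein 3. The members with the smallest p were ACSL1 (0.33), AGPAT2 (0.37) and CD36 (0.48). Fatty acid and triglyceride synthesis had a median of -0.06, a mean of 0.01 and an adjusted p of 0.930 over 21 genes, so that median and mean differed in sign. The median was -0.26 without Japanese Black 3, -0.16 without Holstein 3 and 0.06 without Japanese Black 1 or 2. Its members with the smallest p were ME1 (0.51), DGAT1 (0.31) and ACACA (-0.36).

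Fatty acid uptake and oxidation was called higher in Japanese Black. Of its 25 measured genes 18 were higher and 7 lower, the median log2 difference was 0.21 and the adjusted p was 0.0127. The call was lost with an estimated correlation (adjusted p = 0.808). ANGPTL4, a secreted inhibitor of lipoprotein lipase, passed when adjusted over the list alone (adjusted p 0.0102) but not over all probe sets (0.148). Its signal was 282 ± 5.79 (SD, n = 3) in Japanese Black and 145 ± 19.9 (SD, n = 3) in Holstein, a log2 difference of 0.90 (SE 0.16). ACADM, a dehydrogenase of fatty acid oxidation, had a difference of 0.50 (SE 0.17), PPARGC1A, a coactivator of mitochondrial genes, 1.11 (SE 0.46) and CPT2 0.47 (SE 0.22). Without Holstein 1 the list's adjusted p was 0.122 and its median 0.12. Without Japanese Black 3 the adjusted p was 0.0585, and without Holstein 3 the median was 0.11. After quantile normalization the median was 0.13 (adjusted p 0.0349).

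Respiratory chain genes and the citric acid cycle were not called. Oxidative phosphorylation had 41 of 54 genes lower in Japanese Black, with a median of -0.07 and an adjusted p of 0.117. The median was -0.20 without Japanese Black 3 (adjusted p 3.42e-06), -0.01 without Japanese Black 1 (0.468) and 0.01 without Japanese Black 2 (0.965). Array weights gave a call (adjusted p 0.00249). COX7A2 (0.74) and NDUFB5 (0.42) had its smallest p. The citric acid cycle had a median of 0.08 over 16 genes (adjusted p 0.569), with SUCLA2 (0.30) and DLAT (0.26) first. Its median was -0.04 without Japanese Black 3 and 0.19 without Holstein 2. Glycolysis and glycogen metabolism had a median of -0.02, a mean of 0.02 and an adjusted p of 0.930 over 22 genes, with PGM1 (-0.26) and LDHB (0.47) first. In these 3 lists 0 genes passed, also when adjusted over each list alone.

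Fibre type genes showed no common direction. Slow-twitch genes had a median of 0.05, a mean of -0.07 and an adjusted p of 0.930 over 16 genes. Within that list MYL3, a ventricular and slow myosin light chain, read 2207 ± 939 (SD, n = 3) in Japanese Black and 5110 ± 1039 (SD, n = 3) in Holstein. Its log2 difference of -1.29 (SE 0.32) passed when adjusted over the list alone (adjusted p 0.0472), not over all probe sets (0.287). MYL6B had a difference of 1.48 (SE 0.46), LMCD1 -1.49 (SE 0.54) and MYL2 0.19 (SE 0.08). Fast-twitch genes had a median of 0.04, a mean of -0.03 and an adjusted p of 0.930 over 13 genes. ACTN3, the actinin of fast fibres, had a difference of -0.34 (SE 0.09) with an adjusted p of 0.0697 over the list alone.

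Heat shock and chaperone genes were called higher in Japanese Black, with 17 of 24 genes higher, a median of 0.19 and an adjusted p of 0.0127 (adjusted p = 0.808 with an estimated correlation). Single members did not pass, also when adjusted over the list alone. DNAJB1 had a difference of 1.16 (SE 0.41), CHORDC1 0.77 (SE 0.25), HSPH1 0.65 (SE 0.24) and the small heat shock protein gene HSPB3 -0.64 (SE 0.22). The adjusted p was 0.292 without Japanese Black 2 and 0.147 without Holstein 2. After quantile normalization the median was 0.10 (adjusted p 0.0214).

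Immediate early genes, which respond within minutes to stimulation of a cell, were called lower in Japanese Black, with 17 of 18 genes lower, a median of -0.44 and an adjusted p of 0.00175 (adjusted p = 0.808 with an estimated correlation). The genes with the smallest p were IER3 (-1.11, SE 0.32), JUND (-0.53, SE 0.20), NR4A1 (-0.49, SE 0.21) and FOSL2 (-0.55, SE 0.23), and 0 members passed. The mean level of the list was 0.78 above the mean of all arrays in Holstein 3 and between -0.35 and 0.06 in the other animals. Without Holstein 3 the median was -0.10 and the adjusted p 0.193.

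Cytosolic ribosomal protein genes had 53 of 61 members lower in Japanese Black, with a small median of -0.12, an adjusted p of 0.000195 and a call. With an estimated correlation the adjusted p was 0.808, and after quantile normalization it was 0.0713 with a median of -0.06. RPL3 (-0.39, SE 0.14), RPSA (-0.28), RPL39 (-0.24) and RPL10A (-0.24) had the smallest p, and 0 members passed. The median was -0.07 without Japanese Black 1 and -0.20 without Japanese Black 3, with a call in all 6 leave-one-out fits.

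Of 6 lists of other cell types and of the tissue around the fibres, 2 were called. Endothelial genes were called lower, with 17 of 19 genes lower, a median of -0.28 and an adjusted p of 0.00234. With an estimated correlation the adjusted p was 0.808, and without Japanese Black 2 it was 0.0991. EGFL7 (-0.61, SE 0.19), ROBO4 (-0.65, SE 0.25), SOX18 (-0.37) and the tight junction gene CLDN5 (-0.52) had the smallest p. Extracellular matrix genes were called lower, with 33 of 45 genes lower, a median of -0.26 and an adjusted p of 0.0282 (adjusted p = 0.808 with an estimated correlation). COL5A3, at 103 ± 15.5 against 205 ± 8.61 (SD, n = 3 each), passed when adjusted over the list alone (adjusted p 0.0190). P4HA1, a hydroxylase for collagen, had a difference of 0.76 (SE 0.20), THBS4 one of 0.48 and OGN one of 0.40, opposite to the list. The matrix list lost its call without Japanese Black 1 (adjusted p 0.157), Japanese Black 2 (0.292) or Holstein 3 (0.0987), with medians of -0.18, -0.11 and -0.16. Fibroblast and progenitor genes had a median of -0.19 and an adjusted p of 0.0840 over 21 genes. In that list THY1 (0.66, SE 0.17) and CLEC3B (-0.59, SE 0.16) passed when adjusted over the list alone, in opposite directions. Smooth muscle and pericyte genes had a median of -0.14 over 13 genes (adjusted p 0.117), with LMOD1 (-0.40) first. Without Japanese Black 3 the fibroblast and smooth muscle lists passed, at medians of -0.35 and -0.52 and adjusted p of 0.00236 and 9.61e-05. Without Japanese Black 2 both medians were -0.04, with an adjusted p of 0.7499 for each. The smooth muscle median was -0.04 without Japanese Black 1 (adjusted p 0.438) and -0.31 without Holstein 1 (0.0558). The fibroblast list also passed with array weights (adjusted p 0.0213), with the dimmer 50% left out (0.0280) and with all probe sets (0.0260), and the smooth muscle list with array weights (0.00995). Erythrocyte genes had a median of -0.22 over 7 genes (adjusted p 0.529), with GYPC (0.30) first, and a median of -0.06 without Japanese Black 3. In the Schwann cell and nerve list of 7 genes, with a median of 0.07 and an adjusted p of 0.445, S100B had a difference of 0.91 (SE 0.26) and passed when adjusted over the list alone (adjusted p 0.0483).

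Among 3 immune lists, 2 were called lower in Japanese Black and the leukocyte list was not. Antigen presentation was called, with 15 of 19 genes lower, a median of -0.30 and an adjusted p of 0.0282. With an estimated correlation the adjusted p was 0.808. PSME1, a proteasome activator subunit, had a difference of -0.51 (SE 0.17) and TAP1, a peptide transporter, -0.42 (SE 0.23). BOLA-DQB had a difference of -1.95 (SE 1.07) that came from Holstein 3, where it read 3151 against 67.6 to 110 in the other animals. Holstein 3 also lay far outside the other animals for BOLA-DQA1, BOLA-DQA2 and BOLA-DQA5 of this list. Their differences were 0.93, 1.21 and -1.68 at their brightest probe sets. The call was lost without Japanese Black 2 (adjusted p 0.292, median -0.11) or Holstein 1 (0.131), and without Holstein 3 the median was -0.17. Interferon response genes were called lower, with 16 of 20 genes lower, a median of -0.26 and an adjusted p of 0.0341. With an estimated correlation the adjusted p was 0.808. IRF7 (-0.57, SE 0.17), IFIT2 (-0.54, SE 0.17), ZNFX1 (-0.36) and IRF9 (-0.45) had the smallest p. The mean level of this list was 0.63 above the mean of all arrays in Holstein 3. Without that animal the median was 0.02 and the adjusted p 0.570, and without Japanese Black 2 they were -0.10 and 0.292. They were -0.41 and 0.0209 without Japanese Black 3, and -0.35 and 0.00171 without Holstein 2. The call was also lost with quantile normalization (adjusted p 0.0914) and array weights (0.0808). Leukocyte genes had 19 of 24 lower, a median of -0.17 and an adjusted p of 0.0781, with S100A8 (1.43, SE 0.58) and CD8A (-0.42, SE 0.17) first. Holstein 3 had the highest level of that list, 0.37 above the mean of all arrays. The median was -0.31 without Holstein 1 (adjusted p 0.00483), -0.36 without Japanese Black 3 (0.0209), -0.11 without Japanese Black 2 (0.292) and -0.05 without Holstein 3 (0.676).

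Regulators of muscle growth and turnover were not called with 1 probe set per gene. Myogenic and growth regulators had a median of -0.21 over 26 genes and an adjusted p of 0.194. Without Japanese Black 2 the median was -0.10 (adjusted p 0.7499), and with all probe sets of the listed genes the list was called (0.0461). GHR passed when adjusted over that list alone (adjusted p 0.00290), at the probe set described above; MYF6 (-0.77, SE 0.23) and IGFBP6 (-0.79, SE 0.27) followed. Muscle protein breakdown had a median of -0.03 over 28 genes (adjusted p 0.930). FBXO32, a ubiquitin ligase of muscle atrophy, had a difference of 0.94 (SE 0.28), PSME4 0.56 (SE 0.16), SQSTM1 -0.36 (SE 0.11) and the metallothionein gene MT2A -0.84 (SE 0.28). Insulin signalling and glucose uptake had a median of 0.03, a mean of -0.01 and an adjusted p of 0.930 over 17 genes, with PIK3CA (0.73, SE 0.22) and EIF4EBP1 (-0.74, SE 0.26) first. Circadian clock genes had a median of -0.07 over 7 genes and an adjusted p of 0.671, while the test statistic pointed toward higher levels. There HLF (0.71, SE 0.17) passed when adjusted over the list alone (adjusted p 0.0186).

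**Figure D3:**
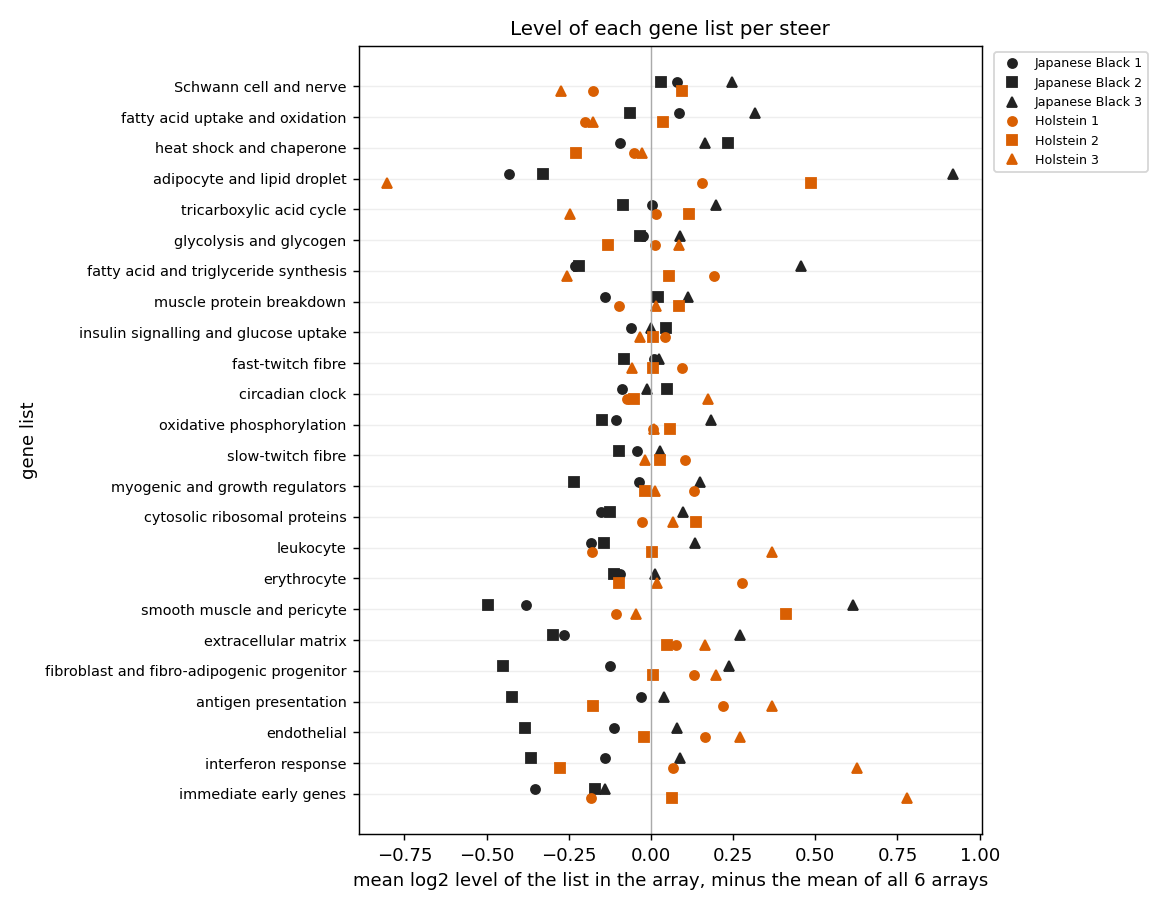
Mean log2 level of each of 24 gene lists (y axis) in each steer, given as the difference from the mean of all 6 arrays (x axis), with a colour for each breed and a marker shape for each replicate. Holstein 3 stands at 0.78 for immediate early genes and -0.80 for adipocyte genes, where Japanese Black 3 stands at 0.92.

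In all, 8 of 24 lists were called with a preset inter-gene correlation of 0.01, 2 higher and 6 lower in Japanese Black, and 0 with an estimated correlation or with fry; 10 lists had an unadjusted camera p under 0.05. Of the 10 splits of the animals into 3 and 3, 5 gave 8 or more called lists, the breed split among them. Over all probe sets, 0 listed genes passed. Among the lists not called, the median also changed sign in a leave-one-out fit for glycolysis (-0.07 to 0.05), slow-twitch fibre (-0.02 to 0.09), protein breakdown (-0.07 to 0.01), insulin signalling (-0.02 to 0.07), circadian clock (-0.16 to 0.11) and Schwann cell genes (-0.01 to 0.30). Among the called lists, leaving out Japanese Black 3 moved the median to -0.38 for extracellular matrix and for endothelial genes and to -0.43 for antigen presentation, and leaving out Holstein 1 moved it to -0.64 for immediate early genes. An exact permutation test of each list's mean level over 3 against 3 animals, two-sided, cannot give a p below 0.1, and its smallest value was 0.2.

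The arrays resembled each other closely. Pearson correlations of the log2 values across probe sets ranged from 0.964 to 0.980 within breeds and from 0.940 to 0.976 between breeds. Holstein 3 had the lowest mean correlation with the other arrays, 0.955, where the others had 0.965 to 0.973. The first principal component held 41.5% of the variance and placed Holstein 3 at 49.6, Holstein 1 and 2 at 10.02 and -0.38, and the Japanese Black animals at -10.7, -15.5 and -33.1. The geometric mean of the bacterial hybridisation controls was 682, 691 and 785 in the Japanese Black animals and 787, 821 and 1169 in the Holstein animals, so it was higher in every Holstein array and highest in Holstein 3. Ratios of 3′ to 5′ control probe sets, a measure of RNA integrity, did not move together. For actin they were 1.11 to 1.14 in Japanese Black and 1.003 to 1.07 in Holstein, without overlap. For GAPDH they were 0.858 to 0.928 and 0.796 to 0.884, with Holstein 3 lowest for both genes. For cyclophilin they were 1.95 to 2.15 and 1.95 to 2.26, with Holstein 3 highest.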

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

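The covariate fit described here was chosen after seeing the data; the other alternatives were planned. All 24 named genes kept their direction in each of the 420 comparisons with an alternative. The rule took only genes whose breeds did not overlap. Offsets, filters, variance models, array weights and left-out arrays therefore could not reverse a direction, so this is no further support. Only ASIP and RRAD had a call to lose. ASIP passed in 9 of its 18 comparisons and RRAD in 8 of 18, which made 19 lost calls. Among the other genes 5 calls were gained. ASIP ranged from 1.54 to 3.004 (adjusted p 0.0127 to 0.385) and RRAD from -1.31 to -1.12 (0.0127 to 0.385). Of the 454 list values, 32 lost a call. All of these were in the 8 called lists, each of which passed in 13 to 16 of 19 settings. Lists without a call gained one in 11 values. In 30 values the median had the opposite sign, of which 1 in a called list, interferon response without Holstein 3.

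The count of 3 probe sets became 0 with an offset of 1, 0 with the dimmer 50% left out, 0 with the unpaired t-test and 0 with the adipocyte level as a covariate, which takes a degree of freedom. It was 10 with array weights, 7 at an adjusted p under 0.10, and 0 to 15 in the leave-one-out fits. The pairs of the study could not be used, because the labels do not say which animals form a pair. Over the 6 possible matchings the paired t-test gave 0 to 1 probe sets and limma with pairs as a block 0 to 7. The count of 2267 at an unadjusted p under 0.05 was 1350 to 2632 in the leave-one-out fits, lowest without Holstein 3. In the unpaired fits more were higher than lower in Japanese Black, except without Japanese Black 3 (800 against 1125). The count was 1806 with the unpaired t-test, 1268 to 1692 with the paired t-test, and 931 with 1 probe set per gene, where 8050 were tested. The 8 lists became 0 with an estimated correlation, 0 with fry and 0 with fry in either direction, and 3 to 11 in the leave-one-out fits, lowest without Japanese Black 2. Apart from fewer arrays or probe sets in some fits, the cause was not tested.

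The robust variance model was not run for the lists because camera has no such option. Dim probe sets limit the folds: ASIP in Holstein lies near the offset, so its fold moves with it.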

Other observations

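The tests of ASIP, Holstein 3 and the immediate early genes reported here were chosen after the results were seen; the splits of the animals were planned. Class II histocompatibility genes, which present peptides on immune cells, set Holstein 3 apart from the other 5 animals. All 12 tested DQ probe sets lay outside the others by more than 4-fold, 8 of them below and 4 above; some of these probe sets belong to the same gene and are not independent. BOLA-DQB read 3151 against 67.6 to 110 and BOLA-DQA5 882 against 10.2 to 25.9. BOLA-DQA2 read 8.99 at its brightest probe set against 287 to 852. For BOLA-DQB1, 1 probe set was listed at 0 against 440 to 789, while another read 775 against 0.900 to 8.33. Over all tested probe sets, Holstein 3 lay more than 4-fold below the lowest other animal at 48. It lay more than 4-fold above the highest at 6, of which 4 were DQ probe sets. Counted in the same way, the other 5 arrays had 6 to 21 below and 1 to 8 above.

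Lower class II expression in that animal is argued against by BOLA-DRA, which read 2363 there and at most 1663 elsewhere. A mislabelled Japanese Black sample is argued against by the 100 probe sets that best separated the breeds in the other 5 arrays: Holstein 3 lay closer to the Holstein mean at 82% of them. Each array was left out in the same way, which gave 21% to 35% for the Japanese Black arrays, 62% for Holstein 1 and 40% for Holstein 2. Holstein 2 was thus closer to the Japanese Black mean at 60% of its probe sets, so the measure did not place every array with its breed. A sample from outside these breeds is not excluded. What stays open is a DQ haplotype that the probe sets read unequally, which may lower some probe sets and raise others. The 4 probe sets above and 8 below are what led to this hypothesis, so they do not test it, and no genotype was analysed here. The class I probe sets are open to the same question: BOLA-N differed by 2.99 between the breeds, while the BOLA probe set differed by 0.36 and those of B2M by -0.13 to -0.19.

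The higher ASIP signal in Japanese Black could come from more fat cells in those samples. Relative to the array mean, the adipocyte list level was -0.43, -0.33 and 0.92 in Japanese Black and 0.15, 0.49 and -0.80 in Holstein. Holstein 2 lay above Japanese Black 1 and 2, yet its ASIP signal was 15.8 against 175 and 152. These values argue against more fat cells, as far as the list measures them. The mean levels of the breeds were close, so a covariate fit could hardly move the ASIP difference. With the adipocyte list level as a covariate the log2 difference was 2.39 (SE 0.23), against 2.40 without it. In that fit 37 probe sets followed the covariate at an adjusted p under 0.05. Genes of the list form the covariate, so this count does not show that the fit could move ASIP. The adjusted p became 0.0695, with a degree of freedom fewer and almost the same difference; over all alternatives it ranged from 0.0127 to 0.385. Array brightness is argued against by the median signals of the arrays, which lay between 48.5 and 54.7 intensity units. Quantile normalization gave 2.38 (SE 0.21), but with such close medians it could hardly move the difference. A sequence difference between the breeds under the probes stays open, since 0 further ASIP probe sets exist in the table, and so does a difference in expression between the breeds.

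The lower immediate early genes in Japanese Black may rest on a single animal. Without Holstein 3 the list median was -0.10 in place of -0.44. Genes of the list that vary together between animals are a further candidate explanation: the estimated correlation was 0.49, and with it the adjusted p was 0.808. Sampling or handling of that animal was not tested, and a difference between the breeds stays open.

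With 3 animals per breed there are 10 splits, too few to tell whether chance gives such a count of probe sets. The real split gave 3 probe sets past the threshold, the largest of the 10 (1 of 10 splits), and the highest other split gave 1. At an unadjusted p under 0.05 it gave 2267 and the highest other 1159. It gave 8 lists, the highest other split gave 9, and 5 of the 10 splits gave 8 or more. Splits that mixed the breeds thus gave as many called lists, so the count of 8 does not set the breeds apart.

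Probe sets of the same gene were also set side by side. Among 20 probe sets with an unadjusted p under 0.001 whose gene had another tested probe set, the brightest other one had the same sign in 18 and an unadjusted p under 0.05 in 11. Among 151 under 0.01 the sign was the same in 129, or 85.4%, with an unadjusted p under 0.05 in 71. The sign counted as the same even where the other difference was very small, as for ESPL1 (-0.01).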
